A study of Mus musculus with 27 samples.

How the data were processed

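The series measured polyadenylated RNA in mouse E14 embryonic stem cells that had received siRNA against GFP as a control (siGFP), siRNA against Ptbp1 (siPTBP1), or siRNA against Ptbp1 and Ptbp2 together (siPTBP1_PTBP2, called the double knockdown). Each culture was separated into fractions that the labels name cytoplasm (CY), nucleoplasm (NP) and chromatin (CH). The 9 groups of treatment and fraction held 3 libraries each, 27 in all, and the series describes the replicates as biological. Stranded libraries of polyA+ RNA were sequenced. Per the submitters' processing notes the reads were handled with STAR and kallisto on mm10, with no versions given.

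The values used were the deposited table of TPM (transcripts scaled to a fixed library total) per gene, which the authors made. It listed 53379 Ensembl gene IDs, of which 15100 were at 0 in every library. Symbols, coordinates, gene types and the length and GC content of the longest transcript were taken from GENCODE M21 (GRCm38, the same assembly as mm10), which held 53274 of the IDs; the release behind the deposited table is not given in the sources used here. The table held 26 symbols turned into dates, which were restored from the gene ID, and 101 additional IDs shared a symbol with another ID. TPM sums to the same total in every library and keeps no depth, so the number of reads behind each value is unknown and no counting interval is given. A value of exactly 0 can be a failed estimate, so a group at 0 throughout is described as listed at 0 and no fold is given against it. Gene TPM does not separate spliced from unspliced RNA, so intron retention was not analysed here. Reads of overlapping, antisense or paralogous genes cannot be assigned with certainty from gene values, and values of genes with transcripts shorter than 200 nt, which depend strongly on how fragment length is corrected, are named as such.

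Genes with a TPM of at least 1 in at least 3 of the 27 libraries were tested, 20611 in all. Each was fitted on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend and robust settings, two-sided), with 1 mean for each of the 9 groups and 18 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, and every adjusted p of a gene is from limma. All log2 differences are on the log2(TPM + 1) scale, which understates the change of low genes. Levels are means ± SD of TPM with n = 3. The contrasts were siPTBP1 and the double knockdown against siGFP in each fraction, the double knockdown against siPTBP1 in each fraction, each pair of fractions in siGFP, and the difference of each knockdown's effect between CH and CY.

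Whether the replicate numbers pair the samples was checked from the correlation of the libraries' deviations from their group means. Across the 108 pairs of libraries with the same number the correlation was 0.130 at the lowest and 0.365 at the median, whereas libraries that shared neither number nor group had a median of -0.213 and at most 0.286. Each of the 27 libraries correlated best with a library of its own number. The numbers were therefore taken as pairing the samples. The pairing comes from the data, since the labels do not say what a number stands for. The fit without the block is the main one and the fit with replicate number as a block, with 16 residual degrees of freedom, is the alternative; both were written down before the data were examined. Blocked values are given beside many of the calls and counts that they change, but not beside every gene and list.

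Genes are named by a rule. Among called genes with a mean of at least 1 TPM in the fractions compared, no overlap between the libraries of the compared groups, and a symbol that is not a predicted or clone name, the largest log2 differences were taken: 10 higher and 10 lower for each knockdown against siGFP in CY and for CH against CY, and 5 higher and 5 lower for the other contrasts, without the overlap condition for the differences of effects. Ptbp1, Ptbp2 and Ptbp3, all members of the list of PTBP1 splicing targets, and up to 4 members with the smallest adjusted p of any other list described were added. Where only some of these genes are described the others are left out for length, and some genes that the rule names are not reported here.

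The 27 gene lists were: PTB family; PTBP1 splicing targets; splicing regulators of neurons and muscle; SR proteins and Tra2; hnRNP proteins; genes known for nuclear detained introns; pluripotency; formative and primed epiblast; neural progenitor; neuronal cytoskeleton and differentiation; synapse; primitive and visceral endoderm; primitive streak and mesoderm; trophoblast; fibroblast; two-cell-stage-like; SRF and YAP targets; p53 targets; interferon response; ATF4 stress response; cholesterol synthesis; glycolysis; nuclear long noncoding RNAs; cytosolic ribosomal proteins; mitochondrially encoded mRNAs; endoplasmic reticulum chaperones and matrix proteins; and oxidative phosphorylation, nuclear encoded. They were fixed from general knowledge and held 516 members, of which 515 were found in the table. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Members past the gene test were counted over all genes tested and adjusted over the list alone. A list's call means a shift of its members against all other genes, not a call of each member.

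Both knockdowns of a fraction were compared with the same siGFP libraries. Their overlap and correlation are given beside n1 x n2 / N and beside 100 simulated pairs of unchanged groups measured against shared controls; with 3 control libraries the controls could not be divided. Effects in different fractions are given beside 100 simulations, added after the data were seen, in which the fractions of a treatment and number receive the same random weights. The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 20611. With a simulated replicate effect, the fit without the block recovered 8% and 57% of them in CY and 5% and 47% in CH, and the blocked fit 27% and 77% in CY and 24% and 66% in CH. The simulated noise came from a fit without the block and already held the real replicate spread. The added effect counts that spread again, so these shares may be too low. Genes of low TPM were not tested apart. Without the added effect the fit without the block recovered 32% and 75% in CY and 32% and 72% in CH. The blocked fit then recovered 29% and 73% in CY and 30% and 70% in CH. No changed gene had the wrong sign, and false calls were 1.52% to 7.27% of the calls over all simulated settings. A list of 20 genes shifted by 0.5 on the log2 scale passed the camera test, as did 3 of 100 unshifted lists. The simulated genes varied independently, so this does not test the preset correlation for lists whose members vary together.

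Alternatives were a pseudocount of 0.1, no filter on low values (38279 genes), a minimum of 5 TPM (14133 genes), median-ratio scaling, quantile normalization, TPM rescaled without the mitochondrially encoded genes (20709 genes), a fit of only the fractions compared, the replicate block, a culture block in which the fractions of one treatment and replicate number share a random effect (statmod 1.5.0, correlation 0.452), and leaving out each library in turn. Chosen after seeing the data were a replicate block within fraction (12 residual degrees of freedom) and a fit without the replicate 1 libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.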

Results

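Polyadenylated RNA was measured in E14 cells, a mouse embryonic stem cell line kept undifferentiated with LIF on gelatin. The cells were transfected with siRNA and transfected again 24 h later, and were fractionated 48 h after the first transfection. The siRNAs were directed against GFP, which the cells lack, against Ptbp1, or against Ptbp1 and Ptbp2 together. Ptbp1 encodes a polypyrimidine tract binding protein that represses many neuronal and muscle exons, and Ptbp2 encodes its paralog, which takes over during neuronal differentiation. Cytoplasm (CY), nucleoplasm (NP) and chromatin (CH) of each treatment were measured in 3 replicates. The libraries held between 11837 and 19509 genes with a TPM of at least 1. The number of reads behind them is unknown. Mitochondrially encoded RNA made up 0.0416% to 0.111% of the TPM in CY, 9.31% to 22.5% in NP and 0.511% to 1.68% in CH. A single gene, Mir6236, took 0.927% to 8.31% of a library. The fractions separated along the first principal component, which held 67.5% of the variance. Within groups the replicate 1 libraries stood apart: on a component with 39.4% of the variance they all scored at least 38.9, and the replicate 2 and 3 libraries at most -11.4. The closest pair of libraries, replicate 2 of the double knockdown and of siPTBP1 in CY, still differed with an SD of 0.249 on the log2 scale over 7342 genes, so no library was counted as a copy of another. P-values measure the spread between these libraries.

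Ptbp1 RNA fell in CY and NP after both siRNA treatments. Ptbp1 (ENSMUSG00000006498, chromosome 10, 79854427 to 79864771, plus strand, mm10) stood at 549 ± 56.2 TPM in siGFP CY, 123 ± 18.1 after siPTBP1 and 142 ± 50.1 in the double knockdown (SD, n = 3). In NP the levels were 391 ± 98.7, 104.5 ± 27.1 and 106 ± 40.3, and in CH they were 514 ± 156, 243 ± 50.7 and 287 ± 61.8. In CY the log2 difference was -2.15 after siPTBP1 (adjusted p = 0.000853), which left 22.4% of the control level, and -1.99 in the double knockdown (adjusted p = 0.00249). In NP it was -1.89 (adjusted p = 0.00375) and -1.90 (adjusted p = 0.00478). With median-ratio scaling the double knockdown's calls in CY and NP were lost (adjusted p = 0.0518 and 0.0905), as was that of siPTBP1 in NP (0.0908). With a fit of the fractions compared only, siPTBP1 in NP (0.208) and the double knockdown in CY and NP (0.0563 and 0.25) lost theirs. In CH the differences of -1.05 after siPTBP1 (adjusted p = 0.16) and -0.82 in the double knockdown (adjusted p = 0.367) passed only with the replicate block (0.00541 and 0.0303). Ptbp2 (ENSMUSG00000028134, chromosome 3, 119718742 to 119784466, minus strand) had 11.3 ± 6.76 TPM in siGFP CY, 13.9 ± 8.99 after siPTBP1 and 5.43 ± 3.45 in the double knockdown. The corresponding levels were 15.8 ± 6.97, 13.3 ± 6.62 and 9.12 ± 4.85 in NP and 67.5 ± 38.7, 57.5 ± 29.6 and 54.9 ± 27.3 in CH. The difference between the double knockdown and siGFP, -0.93 in CY and -0.78 in NP, passed only with the block (adjusted p = 0.00113 and 0.00714). In CY the replicate 1 libraries held less Ptbp2 than the other 2 of each group: 3.52, 3.51 and 1.45 TPM in siGFP, siPTBP1 and the double knockdown. Ptbp3 (ENSMUSG00000028382, chromosome 4, 59471868 to 59549364, minus strand), the third member of the family, had no call in any knockdown contrast. It had 7.35 ± 3.18 TPM in CY, 14.5 ± 5.68 in NP and 34.5 ± 13.6 in CH of siGFP.

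**Figure D1:**
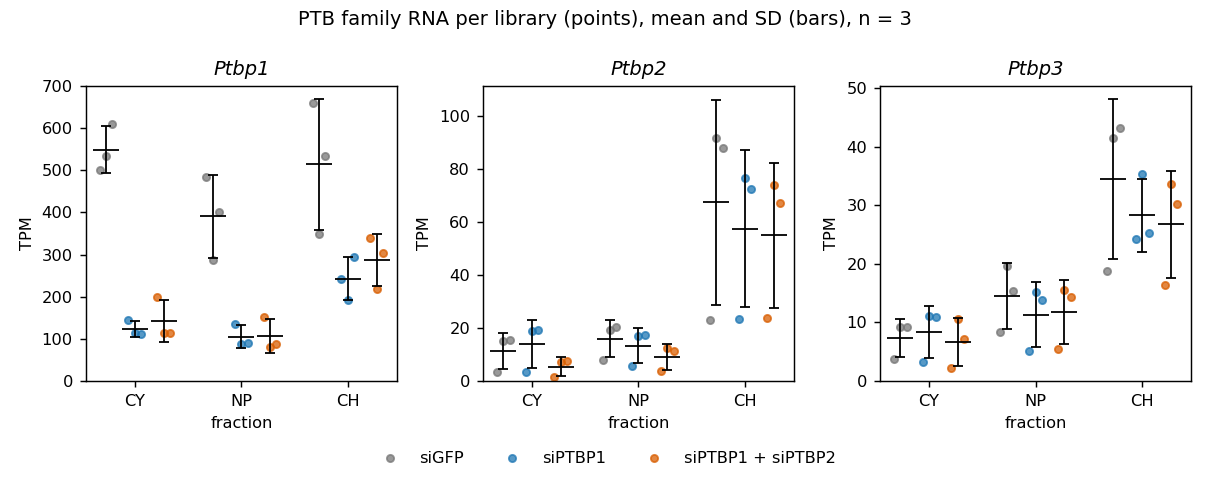
RNA of Ptbp1, Ptbp2 and Ptbp3 in TPM (vertical axis) by fraction (horizontal axis) and treatment (colours); points are libraries, and bars are means with SD of 3. Ptbp1 in CY stood at 549 TPM in siGFP, 123 after siPTBP1 and 142 in the double knockdown.

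The first question was which transcripts changed in the cytoplasm after siRNA against Ptbp1. Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548, minus strand), cardiac alpha-actin, rose from 1.05 ± 0.746 to 52.9 ± 24.5 TPM (log2 difference 4.68, adjusted p = 0.000177). Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand), smooth muscle actin, rose from 4.59 ± 2.07 to 81.5 ± 37.9 (3.86, adjusted p = 0.00073). Myl9 (ENSMUSG00000067818, chromosome 2, 156775420 to 156781658, plus strand), a regulatory myosin light chain, rose from 8.59 ± 4.48 to 101 ± 35.4 (3.48, adjusted p = 0.00215). Myl3, a ventricular myosin light chain, went from 0.68 ± 0.372 to 4.76 ± 0.207 TPM. Vamp2 (ENSMUSG00000020894, chromosome 11, 69088490 to 69092384, plus strand), a synaptobrevin of synaptic vesicle fusion, rose from 16.5 ± 3.48 to 53.4 ± 14 (1.62, adjusted p = 0.00196). Cnih3, an AMPA receptor auxiliary subunit, rose from 0.16 ± 0.0361 to 2.94 ± 0.876 TPM, and Prrt2, a presynaptic membrane protein, from 0.607 ± 0.104 to 4.08 ± 0.739 TPM. Fmnl3 (ENSMUSG00000023008, chromosome 15, 99317225 to 99370482, minus strand), a formin that builds actin filaments, fell from 13.6 ± 0.686 to 2.44 ± 0.45 (-2.09, adjusted p = 6.82e-05), and the related Fhod1 fell from 10.7 ± 0.664 to 2.91 ± 0.313 (-1.58, adjusted p = 0.000853). Tpm1, a tropomyosin, rose by 2.07 (adjusted p = 0.00948), while the filamin Flna (ENSMUSG00000031328, chromosome X, 74223461 to 74249820, minus strand) fell from 61.8 ± 9.28 to 18.7 ± 0.761 (-1.66, adjusted p = 0.00948). The RNA helicase Mov10 fell from 95.5 ± 10.9 to 26.1 ± 5.19 (-1.85, adjusted p = 0.00746). All of these genes moved the same way in every pair of libraries with the same number.

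Among 16 SRF and YAP targets, genes switched on by the transcription factor SRF or the coactivator YAP, 4 rose, none fell and 12 were not called. Adjusted over the list alone 9 rose and 1 fell. The 4 were Acta2, Myl9, Tpm1 and Cnn1 (ENSMUSG00000001349, chromosome 9, 22099216 to 22109630, plus strand), a calponin with 5.72 ± 0.818 TPM in siGFP and 42.7 ± 11.6 after siPTBP1. The median of the list was 1.06 (camera adjusted p = 7.78e-15, adjusted p = 0.0319 with an estimated correlation, 0.159 with that and the block), and 7 rose with the block. Of 14 PTBP1 splicing targets, genes whose splicing is known to be regulated by PTBP1, 3 rose, Vamp2 and Tpm1 among them, 1 fell, which was Flna, and 10 were not called. Adjusted over the list alone 6 rose and 1 fell. The list was shifted upward (camera adjusted p = 6.86e-07, adjusted p = 0.0478 with an estimated correlation, 0.159 with that and the block), and 6 rose with the block. Gabbr1 at 9.13 ± 0.879 against 4.38 ± 0.518 TPM, Sv2a at 2.71 ± 0.151 against 1.04 ± 0.608 and Kif5a at 9.49 ± 2.4 against 3.39 ± 0.985 were called only with the block (adjusted p = 0.019, 0.0128 and 5.06e-05). Of 23 synapse genes, 2 rose, Vamp2 among them, and 21 were not called; adjusted over the list alone 5 rose (camera adjusted p = 1.72e-06, adjusted p = 0.172 with an estimated correlation), and 4 rose with the block. No member was called without the block in 3 lists that were shifted downward: the 25 pluripotency genes with a median of -0.14 (camera adjusted p = 1.59e-05, adjusted p = 0.172 with an estimated correlation), 8 two-cell-stage-like genes (0.000365, adjusted p = 0.318 with an estimated correlation) and 11 interferon response genes (0.00345, adjusted p = 0.172 with an estimated correlation), of which 1 fell with the block. None of the 10 neural progenitor genes was called, 2 were higher adjusted over the list alone and 2 with the block, and the list was shifted upward (camera adjusted p = 0.0185, adjusted p = 0.222 with an estimated correlation). Sox3, a transcription factor of neural progenitors, had 12.5 ± 2.03 against 5.66 ± 1.22 TPM (adjusted p = 0.371, 0.0132 with the block). None of 16 glycolysis genes (camera adjusted p = 0.0185, adjusted p = 0.839 with an estimated correlation; 1 fell with the block) and none of 77 cytosolic ribosomal protein genes (0.0181, adjusted p = 0.91 with an estimated correlation) was called, with both lists shifted downward. Quantile normalization ended the calls of these last 3 lists (adjusted p = 0.0507 for neural progenitor, 0.226 for glycolysis and 0.683 for ribosomal proteins). The PTB family was called downward (camera adjusted p = 0.00102, adjusted p = 0.0319 with an estimated correlation, 0.159 with that and the block), although the median of its 3 members was 0.11, because Ptbp1 alone was called; without the replicate 1 libraries its adjusted p was 0.493.

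The other lists were not called in this contrast and none of their members passed over all genes without the block. With it 2 splicing regulators and 1 gene each of formative and primed epiblast, neuronal cytoskeleton and differentiation, trophoblast and p53 targets rose, and 1 each of formative and primed epiblast and cholesterol synthesis fell. The camera adjusted p was 0.247 for splicing regulators of neurons and muscle, with 2 of 21 higher adjusted over the list alone. It was 0.982 for SR proteins and Tra2, 0.884 for hnRNP proteins, 0.532 for genes known for nuclear detained introns and 0.873 for formative and primed epiblast, where adjusted over the list alone 1 rose and 1 fell. For neuronal cytoskeleton and differentiation it was 0.454, with 1 of 17 higher adjusted over the list alone. Values of 0.512 for both primitive and visceral endoderm and primitive streak and mesoderm, and of 0.884 for trophoblast and for fibroblast, were found for the lineage lists. For the stress and metabolic lists they were 0.247 for p53 targets, with 1 higher adjusted over the list alone, 0.884 for ATF4 stress response, and 0.884 for cholesterol synthesis, with 1 lower adjusted over the list alone. They were 0.349 for nuclear long noncoding RNAs, 0.0819 for mitochondrially encoded mRNAs, 0.682 for endoplasmic reticulum chaperones and matrix proteins, and 0.33 for oxidative phosphorylation, nuclear encoded.

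In all, 33 genes rose and 14 fell in CY after siPTBP1 in the limma test, and 20564 of 20611 were not called. With the replicate block 275 rose and 102 fell, and all 47 genes called without it were among them. The split of calls with median-ratio scaling was 31 higher and 23 lower. Without the replicate 1 libraries, an alternative chosen after seeing the data, 62 rose and 33 fell. The count was 25 without siGFP CY replicate 1, 24 without siGFP CY replicate 3, and 22 without siPTBP1 CY replicate 2 or without siPTBP1 CY replicate 3. Cnn1 (adjusted p = 0.0428) lost its call without any of the 6 libraries compared: 0.14, 0.136 and 0.245 without siGFP CY replicates 1, 2 and 3, and 0.172, 0.107 and 0.247 without siPTBP1 CY replicates 1, 2 and 3. Tpm1 lost it without siGFP CY replicate 1 (0.0767) or siPTBP1 CY replicate 3 (0.0772), and Mov10 without siPTBP1 CY replicate 3 (0.0607) and with quantile normalization (0.0579). Flna lost it without siGFP CY replicate 2 (0.0651), siPTBP1 CY replicate 2 (0.0512) or siPTBP1 CY replicate 3 (0.0601), and with quantile normalization (0.115). A fit of the fractions compared only, which has fewer libraries to estimate the spread from, ended the calls of Vamp2 (0.118), Acta2 (0.102), Myl9 (0.0892), Prrt2 (0.137), Tpm1 (0.37) and Mov10 (0.126).

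**Figure D2:**
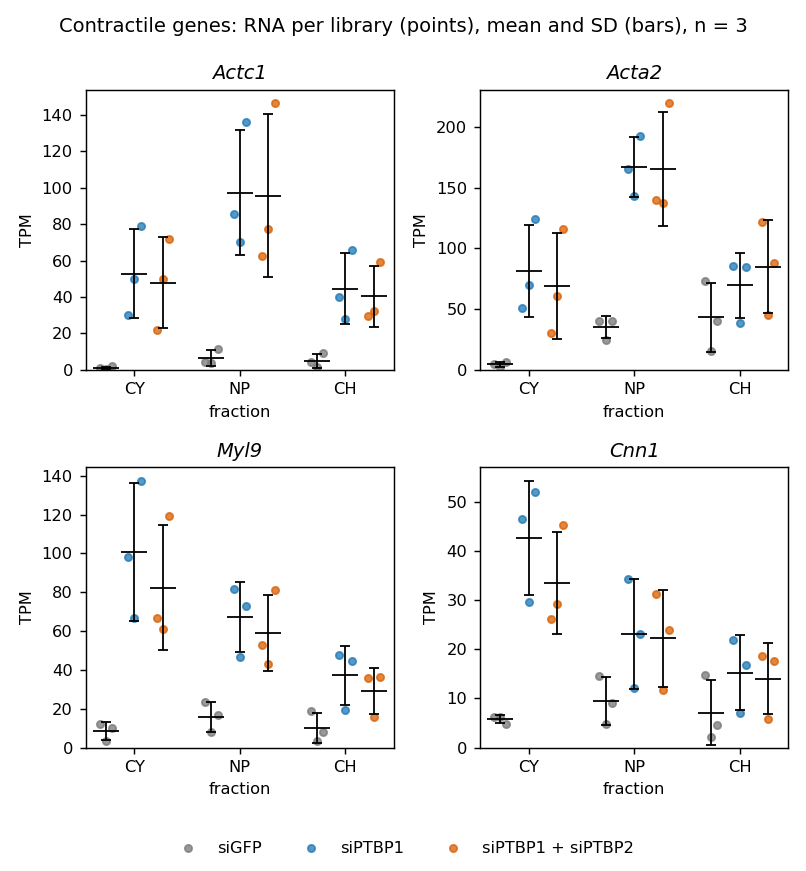
RNA of Actc1, Acta2, Myl9 and Cnn1 in TPM (vertical axis) by fraction (horizontal axis) and treatment (colours); points are libraries, and bars are means with SD of 3. In CY, Actc1 stood at 1.05 TPM in siGFP, 52.9 after siPTBP1 and 47.9 in the double knockdown.

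In the nucleoplasm, Actc1 rose from 6.45 ± 4.41 to 97.2 ± 34.3 TPM after siPTBP1 (3.82, adjusted p = 0.00182; 0.0617 without the replicate 1 libraries). Atp6v1g2 (ENSMUSG00000024403, chromosome 17, 35233660 to 35238767, plus strand), a subunit of the vesicular proton pump, rose from 0.477 ± 0.186 to 5.09 ± 1.69 (2.02, adjusted p = 0.000793), and Myl3 from 0.56 ± 0.451 to 4.66 ± 0.543 (1.90, adjusted p = 0.000367). Gpc2, a glypican of the developing nervous system, rose from 8.32 ± 2.26 to 30.6 ± 6.58 (1.77, adjusted p = 0.00154). Sv2a (ENSMUSG00000038486, chromosome 3, 96181151 to 96195521, plus strand), a synaptic vesicle glycoprotein, rose from 5.64 ± 1.56 to 15.8 ± 2.62 (1.35, adjusted p = 0.00434; 0.0622 without siPTBP1 NP replicate 2). Iqgap1, a scaffold of cortical actin, fell from 34.7 ± 4.58 to 10.9 ± 1.12 (-1.58, adjusted p = 0.00598). Flna, at 41.7 ± 9.8 against 124 ± 26 (-1.55, adjusted p = 0.0183), lost its call with median-ratio scaling (0.179), with quantile normalization (0.109), and without siGFP NP replicate 1 (0.155), siGFP NP replicate 3 (0.0727), siPTBP1 NP replicate 2 (0.161) or siPTBP1 NP replicate 3 (0.108). With a fit of the fractions compared only it was 0.251 and with the culture block 0.0526, and that fit also ended the calls of Myl3 (0.0521), Gpc2 (0.078) and Sv2a (0.19). Snord98, a small nucleolar RNA inside a host gene, was listed at 0 in all siPTBP1 libraries and at 4.89, 4.15 and 7.64 TPM in siGFP (adjusted p = 0.00154). Vamp2 at 39.2 ± 4.05 against 23.2 ± 5.4 TPM was called only with the block (adjusted p = 0.03).

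Among 20 endoplasmic reticulum chaperones and matrix proteins, RNAs translated at that membrane, none was called, but the list was shifted upward with a median of 0.51 (camera adjusted p = 1.47e-07, adjusted p = 0.233 with an estimated correlation). Lamb1, a laminin chain, had 129 ± 11.5 against 73.3 ± 7.71 TPM, and Sec61a1, the translocon channel, 507 ± 91.1 against 316 ± 43.9 (adjusted p = 0.0431 with the block). The same list was enriched in NP over CY in siGFP, with a median of 3.20. None of 14 primitive and visceral endoderm genes, which share laminin chains with that list, was called (upward, 1.31e-05, adjusted p = 0.0655 with an estimated correlation). No SRF and YAP target was called; adjusted over the list alone 2 rose and 1 fell, and with the block 3 rose and 1 fell (upward, 6.17e-07, adjusted p = 0.16 with an estimated correlation). Of the synapse genes Sv2a rose, and with the block 3 did (upward, 7.67e-05, adjusted p = 0.233 with an estimated correlation). Of the PTBP1 splicing targets Sv2a rose and Flna fell, 6 rose and 1 fell adjusted over the list alone, and 4 rose and 1 fell with the block (upward, 0.0244, adjusted p = 0.473 with an estimated correlation, 0.0809 with the block). The pluripotency list was shifted downward with no member called, and 1 fell with the block (2.24e-06, adjusted p = 0.156 with an estimated correlation). So was interferon response, with 2 lower adjusted over the list alone and 3 lower with the block (3.8e-05, adjusted p = 0.0655 with an estimated correlation). Isg15, a ubiquitin-like protein of that response, had 2.04 ± 0.83 against 7.5 ± 2.27 TPM (adjusted p = 0.136, 0.00162 with the block). Downward shifts with no called member were found for hnRNP proteins (0.000143, adjusted p = 0.51 with an estimated correlation), ribosomal proteins (8.24e-05, adjusted p = 0.51 with an estimated correlation) and glycolysis (0.00256, adjusted p = 0.51 with an estimated correlation; 2 fell with the block). The test found 22 genes higher and 11 lower, with 20578 not called; 247 rose and 141 fell with the block, and 49 rose and 14 fell with median-ratio scaling. The count was 17 without siPTBP1 NP replicate 2 and 21 without siGFP NP replicate 1, and without the replicate 1 libraries 57 rose and 54 fell.

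On chromatin, Actc1 rose from 4.88 ± 3.91 to 44.5 ± 19.4 TPM after siPTBP1 (3.11, adjusted p = 0.0104; 0.0871 without the replicate 1 libraries). Atp6v1g2, Cnih3 and Myl3 also rose there (2.26, 1.23 and 1.63; adjusted p = 0.000102, 0.0125 and 0.000965), so these 4 genes rose in all 3 fractions, and Tmem81 fell in all 3. With the block 27 genes rose and 25 fell in all 3. Trav12d-3 (ENSMUSG00000094607, chromosome 14, 52929789 to 52930282, plus strand), a T cell receptor variable gene segment, was listed at 0 in siGFP CH and at 4.03, 3.75 and 8.82 TPM after siPTBP1 (adjusted p = 6.09e-05). A fit of the fractions compared only ended the calls of Actc1 (0.285) and Trav12d-3 (0.164). Other genes named by the rule were microRNA precursors shorter than 200 nt: Mir6387 was listed at 0 in siGFP and at 6.55, 6.23 and 14.17 TPM after siPTBP1, and Mir7687 at 43.99, 13.65 and 20.31 in siGFP and at 0 after siPTBP1. No SRF and YAP target was called in CH, and 3 rose both adjusted over the list alone and with the block (upward, camera adjusted p = 0.00386, adjusted p = 0.881 with an estimated correlation). Pluripotency, interferon response and glycolysis were shifted downward with no called member (0.00128 each, adjusted p = 0.677, 0.251 and 0.881 with an estimated correlation), and with the block 1, 3 and 1 of their members fell. Oasl2, of the interferon response, had 3.51 ± 0.47 against 8.33 ± 2.84 TPM (adjusted p = 0.254, 0.00962 with the block). The PTB family was called downward (0.047, adjusted p = 0.251 with an estimated correlation; 0.123 with median-ratio scaling). Mitochondrially encoded mRNAs were called upward (0.047, adjusted p = 0.96 with an estimated correlation; 0.126 with the block), and without the replicate 1 libraries their direction turned (0.747). In all 56 genes rose, 26 fell and 20529 were not called, and 14 of the higher and 12 of the lower genes had transcripts under 200 nt. With the block 375 rose and 130 fell. The calls divided into 27 higher and 21 lower with median-ratio scaling and 32 and 23 with quantile normalization. The count was 184 without siPTBP1 CH replicate 1, and 131 rose and 51 fell without the replicate 1 libraries.

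Across genes, the siPTBP1 effects in CY and NP correlated with r = 0.324, those in CY and CH with 0.231 and those in NP and CH with 0.185; genes are not independent replicates, and no p is given. Fractions of the same treatment and number may come from the same cells, which raises these values without any effect. In 100 simulations of unchanged treatments that keep what such fractions share, r averaged 0.0647, 0.0514 and 0.0126, with maxima of 0.209, 0.202 and 0.0803. The covariances were 0.0367, 0.0313 and 0.0289, against simulated means of 0.00545, 0.00675 and 0.00189, and 1, 4 and 0 of the simulations reached them. Over the 640, 788 and 796 genes called with the block in either fraction of each pair, which were thus chosen for a large effect, r was 0.754, 0.342 and 0.395, and 96.7%, 83.9% and 83.5% had the same sign. Without the block CY and NP shared 4 higher and 9 lower genes, against 0.0352 and 0.00747 for independent lists, and CH shared 6 higher and 1 lower with either of them. With the block CY and NP shared 64 higher and 61 lower genes (3.30 and 0.698 for independent lists), CY and CH 63 and 29 (5.003 and 0.643), and NP and CH 61 and 34 (4.49 and 0.889). The simulated treatments shared at most 0, 0 and 3 genes, and 12, 48 and 12 with the block, in these 3 pairs of fractions.

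The double knockdown asked whether siRNA against Ptbp2 as well adds to the response. In CY it moved largely the same named genes: Actc1 rose to 47.9 ± 25 TPM (4.49, adjusted p = 0.000263), Acta2 to 69.1 ± 43.5 (3.52, adjusted p = 0.00228), Myl9 to 82.4 ± 32.1 (3.19, adjusted p = 0.00523; 0.0631 with quantile normalization) and Vamp2 to 55.1 ± 11.3 (1.68, adjusted p = 0.00176). Fmnl3 fell to 2.73 ± 0.65 (-1.98, adjusted p = 8.51e-05). Myo1d (ENSMUSG00000035441, chromosome 11, 80482126 to 80780025, minus strand), an unconventional myosin, fell from 4.51 ± 1.07 to 0.72 ± 0.234 (-1.67, adjusted p = 1.67e-05), and Tyms (ENSMUSG00000025747, chromosome 5, 30058202 to 30073617, minus strand), thymidylate synthase, from 134 ± 9.57 to 39 ± 18.5 (-1.87, adjusted p = 0.00131). Iqgap1 fell to 5.95 ± 2.59 from 19.8 ± 8.06 (-1.57, adjusted p = 0.00523; 0.0503 without siGFP CY replicate 3). A fit of the fractions compared only ended the calls of Actc1 (0.0571), Acta2 (0.124), Myl9 (0.107), Vamp2 (0.114), Tyms (0.183) and Iqgap1 (0.295). Cnn2 at 179 ± 41.1 against 39.3 ± 6.65 TPM, Cnn1 at 33.6 ± 10.4 and Tpm1 at 214 ± 129 passed only with the block (adjusted p = 3e-05, 0.000594 and 0.025). Acta2 and Myl9 were the 2 SRF and YAP targets that rose; 7 rose and 1 fell adjusted over the list alone, as with the block (upward, camera adjusted p = 2.62e-09, adjusted p = 0.0886 with an estimated correlation). Of the PTBP1 splicing targets 2 rose, Vamp2 among them, and Flna fell to 21.9 ± 3.34 TPM (6 and 1 adjusted over the list alone, 6 and 2 with the block; upward, 5.15e-06, adjusted p = 0.0886 with an estimated correlation, 0.274 without the replicate 1 libraries). The call of Flna (adjusted p = 0.0295) was lost with median-ratio scaling (0.167), quantile normalization (0.214), no filter (0.0551) and the culture block (0.0617). It was also lost without siGFP CY replicates 1, 2 or 3 (0.115, 0.179 and 0.0726) or replicates 2 or 3 of the double knockdown (0.126 and 0.146). Of the synapse genes 2 rose, again with Vamp2, and 4 rose adjusted over the list alone and 5 with the block (upward, 2.62e-09, adjusted p = 0.0886 with an estimated correlation). No pluripotency gene was called without the block and 5 fell with it (downward, 2.78e-06, adjusted p = 0.13 with an estimated correlation); among them Nanog, a core pluripotency factor, had 77.8 ± 41.5 against 138 ± 28.4 TPM (adjusted p = 0.0385 with the block) and Prdm14 3.64 ± 1.1 against 6.51 ± 1.29 (0.0176 with the block). Downward shifts with no called member were found for ribosomal proteins (6.56e-06, adjusted p = 0.51 with an estimated correlation; 0.0589 with quantile normalization), two-cell-stage-like genes (0.000199, adjusted p = 0.302 with an estimated correlation) and interferon response (0.0175, adjusted p = 0.302 with an estimated correlation; 2 fell with the block). Neural progenitor genes were shifted upward with none called (0.0121, adjusted p = 0.191 with an estimated correlation; 2 rose with the block), and SR proteins and hnRNP proteins, with no member called, passed only with the block (0.0421 and 0.0204, 0.809 each when an estimated correlation was added).

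In NP of the double knockdown Actc1 stood at 95.6 ± 44.7 TPM (3.75, adjusted p = 0.0023; 0.0538 without the replicate 1 libraries), Atp6v1g2 at 4.85 ± 0.817 (1.98, adjusted p = 0.00137), Gpc2 at 28.6 ± 3.3 (1.69, adjusted p = 0.0023) and Sv2a at 17.2 ± 1.46 (1.48, adjusted p = 0.0023). Tyms fell from 88.6 ± 9.69 to 28 ± 6.55 (-1.64, adjusted p = 0.00478). Snord98 was again listed at 0 throughout NP, but at 86.47, 258.43 and 164.88 TPM in CH of the double knockdown. A fit of the fractions compared only ended the calls of Actc1 (0.0618), Atp6v1g2 (0.0618), Gpc2 (0.119), Sv2a (0.136) and Tyms (0.0679). Endoplasmic reticulum chaperones and matrix proteins were shifted upward, with none called and a median of 0.45 (2.56e-06, adjusted p = 0.273 with an estimated correlation; 1 rose with the block). So were mitochondrially encoded mRNAs (0.000323, adjusted p = 0.406 with an estimated correlation; 0.0581 with quantile normalization). Upward shifts were found as well for synapse genes, of which Sv2a rose (6.51e-05, adjusted p = 0.273 with an estimated correlation), and for SRF and YAP targets (7.41e-05, adjusted p = 0.273 with an estimated correlation) and primitive and visceral endoderm (0.000188, adjusted p = 0.14 with an estimated correlation), with none called. Ribosomal proteins (1.16e-09, adjusted p = 0.273 with an estimated correlation), pluripotency (2.76e-05, adjusted p = 0.254 with an estimated correlation) and interferon response (9.07e-05, adjusted p = 0.137 with an estimated correlation) were shifted downward with no member called. With the block 1, 1 and 2 of their members fell, 3 synapse genes rose, and 3 SRF and YAP targets rose and 1 fell.

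On chromatin of the double knockdown Actc1 rose to 40.3 ± 16.6 TPM (2.99, adjusted p = 0.0184; 0.0815 without the replicate 1 libraries, 0.0577 without siGFP CH replicate 2 and 0.0829 without double knockdown CH replicate 3). Atp6v1g2 rose from 2.32 ± 0.84 to 15 ± 3.78 (2.27, adjusted p = 7.61e-05), and Trav12d-3 was at 3.54, 5.06 and 10.66 TPM (adjusted p = 1.15e-05). A fit of the fractions compared only ended the calls of Actc1 (0.4), Atp6v1g2 (0.102) and Trav12d-3 (0.173). Ribosomal proteins (1.18e-07, adjusted p = 0.682 with an estimated correlation), oxidative phosphorylation (9.46e-06, adjusted p = 0.722 with an estimated correlation), pluripotency (9e-05, adjusted p = 0.456 with an estimated correlation) and interferon response (9e-05, adjusted p = 0.222 with an estimated correlation) were shifted downward with no member called; 1 pluripotency and 2 interferon response genes fell with the block. Actc1, Cnih3 and Myl3 rose in all 3 fractions of the double knockdown, and Myo1d and Tmem81 fell in all 3. With the block these counts were 34 and 20. In CH the call of Tmem81 (adjusted p = 0.0318) was lost without siGFP CH replicate 2 (0.0648), siGFP CH replicate 3 (0.106) or double knockdown CH replicate 2 (0.119). It was lost as well with a pseudocount of 0.1 (0.29), a TPM of at least 5 (0.0799), the culture block (0.105) and a fit of the fractions compared only (0.956).

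The double knockdown raised 31 and lowered 19 genes in CY, 19 and 13 in NP, and 67 and 21 in CH, with 20561, 20579 and 20523 not called. With the block the counts were 351 and 196, 234 and 145, and 338 and 98, and without the replicate 1 libraries 60 and 41, 42 and 51, and 137 and 61. The split with quantile normalization was 29 and 27 in CY and 35 and 18 in CH, and with median-ratio scaling 42 and 13 in NP and 26 and 15 in CH; without the mitochondrially encoded genes it was 29 and 12 in NP. The count in CY was 21 without siGFP CY replicate 3 and 27 without double knockdown CY replicate 2. In NP it was 20 without siGFP NP replicate 1 and 19 without double knockdown NP replicate 2, and in CH 181 without double knockdown CH replicate 1 and 50 without double knockdown CH replicate 3. Both knockdowns shared 23 higher and 11 lower genes in CY, 16 and 11 in NP, and 27 and 8 in CH, where independent lists of these sizes (n1 x n2 / N) would share 0.0496 and 0.0129, 0.0203 and 0.00694, and 0.182 and 0.0265; no gene was called in opposite directions. With the block they shared 185 and 77 in CY, 170 and 106 in NP, and 213 and 53 in CH, where independent lists would share 4.68 and 0.970, 2.80 and 0.992, and 6.15 and 0.618, again with 0 in opposite directions. In 100 simulations of unchanged groups that share controls and keep the replicate effects, the lists shared 0.03, 0.05 and 3.54 genes on average and at most 1, 2 and 122, so the number shared in CH lay within the simulated range. With the block the means were 0.02, 0.05 and 4.67 and the maxima 1, 2 and 200, below the numbers shared in every fraction. Across genes the effects of both treatments correlated with r = 0.667 in CY, 0.735 in NP and 0.622 in CH, against means of 0.433, 0.440 and 0.436 and maxima of 0.968, 0.962 and 0.967 in the simulations. The covariances were 0.0717, 0.101 and 0.115, against simulated means of 0.0352, 0.0401 and 0.0768 and maxima of 0.159, 0.165 and 0.369. The observed correlations and covariances, which the block does not alter, thus lay within the range of unchanged groups. The 3 controls could not be divided, so the shared siGFP libraries may account for part or all of them, and genes are not independent replicates.

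Set directly against siPTBP1, the double knockdown gave few calls, which does not show that both are alike. In simulated tests of siPTBP1 against siGFP in CY and CH, 5% to 32% of log2 changes of 1 were recovered. Shares with an added replicate effect (5% to 27%) may be too low. Genes of low TPM were not tested apart. In CY no gene was called by limma. Only 147 genes had an unadjusted p under 0.05, a share of all genes below 0.05 (821 with the block). The fit without the block was thus probably too strict. With the block 1 gene was called, Ptbp2, which fell by 1.13 on the log2 scale (adjusted p = 0.00506). The count was 3 without siPTBP1 CY replicate 3, 1 without double knockdown CY replicate 1 and 2 without double knockdown CY replicate 2. In NP the 1 called gene, the predicted Gm22297 (ENSMUSG00000065246), which is outside the rule for named genes and was chosen after its values were seen, fell by 2.65 (adjusted p = 0.0204). With median-ratio scaling or without the mitochondrially encoded genes 1 gene rose and 1 fell, and with quantile normalization none was called. There the count was 0 without siPTBP1 NP replicate 1, siPTBP1 NP replicate 2 or double knockdown NP replicate 1, 6 without siPTBP1 NP replicate 3, and 2 without double knockdown NP replicate 3. In CH 14 genes rose and 8 fell, of which 11 and 5 had transcripts under 200 nt; with the block 9 rose and 8 fell, and 16 of the 22 were among them. Mir6387 was listed at 0 in the double knockdown (adjusted p = 0.000294), and Mir7647 at 0 in siPTBP1 and at 7.51, 15.46 and 19.85 TPM in the double knockdown (adjusted p = 0.0114; 0.143 with the culture block and 1 with a fit of the fractions compared only). Zfp935, a zinc finger protein, fell from 2.5 ± 0.438 to 0.143 ± 0.248 TPM (-1.63, adjusted p = 0.00875; 0.25 without the replicate 1 libraries, 0.317 with a pseudocount of 0.1, 0.163 with quantile normalization and 1 with a fit of the fractions compared only). The count in CH was 2 with a fit of the fractions compared only, 135 with no filter, 49 without siPTBP1 CH replicate 1, 65 without siPTBP1 CH replicate 2, and 45, 64 and 42 without double knockdown CH replicates 1, 2 and 3. Ribosomal proteins were shifted downward in CH (camera adjusted p = 1.56e-12, adjusted p = 0.548 with an estimated correlation), as were oxidative phosphorylation genes (1.25e-11, adjusted p = 0.548 with an estimated correlation) and mitochondrially encoded mRNAs (1.32e-06, adjusted p = 0.627 with an estimated correlation), with no member called. Without the replicate 1 libraries the call of the mitochondrially encoded mRNAs was lost (0.743). In NP ribosomal proteins were lower (0.00014, adjusted p = 0.977 with an estimated correlation) and mitochondrially encoded mRNAs higher (0.00641, adjusted p = 0.977 with an estimated correlation). In CY 3 list calls were lost with the block: ribosomal proteins (0.0231, adjusted p = 0.967 with an estimated correlation, 0.145 with the block), endoplasmic reticulum (0.0333, adjusted p = 0.967 with an estimated correlation, 0.0748 with the block) and mitochondrially encoded mRNAs (0.0347, adjusted p = 0.967 with an estimated correlation, 0.0963 with the block). Quantile normalization ended both list calls in NP (0.411 each).

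In siGFP cells the fractions were compared. NP was richer than CY in mitochondrially encoded mRNAs and RNAs of endoplasmic reticulum chaperones and matrix proteins. These organelles may be carried into NP, so such RNAs need not be nucleoplasmic. All 13 mitochondrially encoded mRNAs were higher in NP, with a median of 7.70 (camera adjusted p = 3.88e-31). Among them mt-Cytb, of respiratory complex III, stood at 10443 ± 1198 TPM in NP against 44.7 ± 23.3 in CY. mt-Nd1, of complex I, was higher by 7.05. All 20 of the endoplasmic reticulum list were higher, with a median of 3.20 (1.7e-26). Among them were the laminin chains Lamc1 at 155 ± 21.3 against 9.32 ± 2.99 (3.96, adjusted p = 4.68e-10) and Lamb1 at 73.3 ± 7.71 against 4.68 ± 1.55 (3.74, adjusted p = 1.99e-09), and the E-cadherin Cdh1 at 529 ± 83.4 against 41.6 ± 12.3 (3.67, adjusted p = 2.93e-08). Of 14 primitive and visceral endoderm genes 6 were higher (6.18e-09) and of 13 fibroblast genes 7 (7.5e-07). Fn1, fibronectin, stood at 388 ± 130 against 22.6 ± 9.72 TPM (4.08, adjusted p = 9.25e-08). Of 14 nuclear long noncoding RNAs 10 were higher (0.000273, adjusted p = 0.539 with an estimated correlation), including Meg3 at 162 ± 42.2 against 37.4 ± 7.84. Of 19 cholesterol synthesis genes 10 were higher (0.00476, adjusted p = 0.515 with an estimated correlation). Of 77 ribosomal protein genes 8 were lower (6.34e-18, adjusted p = 0.0947 with an estimated correlation; 2 higher and 33 lower with the block), such as Rpl13a (-1.04, adjusted p = 0.00238). In all 2543 genes were higher in NP and 95 lower, against a median of all genes of 0.15 that moved to 0 with median-ratio scaling and -0.13 with quantile normalization. With the block 4853 were higher and 977 lower, with median-ratio scaling 2179 and 661, with quantile normalization 1437 and 802, and without the replicate 1 libraries 3310 and 1125.

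Chromatin held less mRNA of ribosomal proteins than CY. The median of all genes was 0.95 and moved to 0.37 with median-ratio scaling and -0.12 with quantile normalization, so a gene at 0.95 kept its place among the others. Of 77 ribosomal protein genes 69 were lower and 3 higher, with a median of -1.76 (camera adjusted p = 2.48e-49). Rpl32 stood at 599 ± 98.7 against 5165 ± 145 TPM (-3.12, adjusted p = 1.32e-08) and Rps15a at 326 ± 65.2 against 2395 ± 32 (-2.89, adjusted p = 1.47e-09). Rpl12 was higher, at 458 ± 84.5 against 55.2 ± 15.6 (3.05, adjusted p = 6.93e-09). Of 23 nuclear-encoded oxidative phosphorylation genes 18 were lower and 1 higher, with a median of -1.11 (7.07e-16, adjusted p = 0.25 with an estimated correlation). Atp5e, an ATP synthase subunit, stood at 63.2 ± 24.3 against 444 ± 25.4 (-2.86, adjusted p = 1.37e-07). All 14 nuclear long noncoding RNAs were higher, with a median of 3.80 (1.22e-05, adjusted p = 0.508 with an estimated correlation), including Snhg11 at 97.9 ± 35.2 against 0.887 ± 0.401 (5.66). Clk1 at 253 ± 108 against 17.8 ± 6.43 (3.70) and Clk2 at 145 ± 42.2 against 22.5 ± 6.78 (2.63), kinases of SR proteins, were among the 6 of 7 genes known for nuclear detained introns that were higher, but the list was not called (0.197; 0.00918 with quantile normalization). Of the 14 PTBP1 splicing targets 12 were higher, with a median of 2.05 (0.0561; 0.00244 with quantile normalization). Gabbr1 (ENSMUSG00000024462, chromosome 17, 37045966 to 37075067, plus strand), a GABA-B receptor, led them at 189 ± 61.8 against 4.38 ± 0.518 TPM (5.10, adjusted p = 1.22e-12), and Flna stood at 799 ± 345 against 61.8 ± 9.28 (3.59, adjusted p = 1.22e-09). Vamp2 was higher by 2.07, Ptbp2 by 2.46 (adjusted p = 0.00674; 0.0675 with quantile normalization, 0.0537 without siGFP CY replicate 1), and Ptbp1 was not called (-0.14, adjusted p = 0.7). Pluripotency genes went both ways, 7 higher and 8 lower, and the list lay below the other genes (0.00138, adjusted p = 0.508 with an estimated correlation; 0.264 with quantile normalization) although its median was 0.08. Dppa5a (0.0639 with quantile normalization) and Dppa3 were lower by 1.64 and 1.88 on this scale and Stat3 and Il6st higher by 1.71 and 2.17. Of 22 genes of hnRNP proteins 6 were higher and 5 lower. The list had a median of 0.20 and was called below the other genes (0.0121, adjusted p = 0.693 with an estimated correlation). It lost its call with the block (0.107) and turned with quantile normalization (0.859). Among transcripts under 200 nt, 938 were higher; Snord35a stood at 924 ± 187 against 1.35 ± 2.34 TPM, and Snord91a at 298.9, 363.11 and 554.42 in CH and at 0 in CY. In all 11942 genes were higher and 1665 lower; with median-ratio scaling 8194 and 4263, and with quantile normalization 4917 and 6439, where lower calls outnumbered higher ones.

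CH against NP gave 9479 genes higher and 1130 lower, and the median of all genes was 0.68, 0.23 with median-ratio scaling and -0.08 with quantile normalization. With median-ratio scaling 6291 were higher and 2697 lower, and with quantile normalization 3954 and 4702. All 13 mitochondrially encoded mRNAs were lower in CH, with a median of -4.07 (4.88e-20). Of 77 ribosomal protein genes 62 were lower and 5 higher, with a median of -1.31 (5.2e-39), and of 23 oxidative phosphorylation genes 22 were lower, with a median of -1.53 (3.5e-24). All 14 nuclear long noncoding RNAs were higher, with a median of 2.51 (5.57e-06, adjusted p = 0.357 with an estimated correlation). Of the endoplasmic reticulum list 2 were higher and 5 lower (downward, 8.26e-06, adjusted p = 0.357 with an estimated correlation). PTBP1 splicing targets, with 8 of 14 higher and a median of 1.40, and genes known for nuclear detained introns, with 6 of 7 higher and a median of 1.97, were called with the block only (0.0299 and 0.0139, 0.502 and 0.465 when an estimated correlation was added). Gabbr1 was higher by 3.77 and Flna by 2.61. The calls of gene lists that held with an estimated correlation were, for the knockdowns, the PTB family in CY of both and in NP of the double knockdown, and PTBP1 splicing targets and SRF and YAP targets in CY after siPTBP1. For the fractions they were mitochondrially encoded mRNAs, endoplasmic reticulum, primitive and visceral endoderm and fibroblast in NP against CY; ribosomal proteins in CH against CY; and ribosomal proteins, mitochondrially encoded mRNAs and oxidative phosphorylation in CH against NP. The PTB family list holds the siRNA targets. With the block too, only its calls in CY and NP of the double knockdown (adjusted p = 0.00252 and 0.00507) held. Those of siPTBP1 in CY were at 0.159 each and those of the fractions at 0.0767 to 0.186, and the PTB family in NP after siPTBP1 was called (0.0252).

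**Figure D3:**
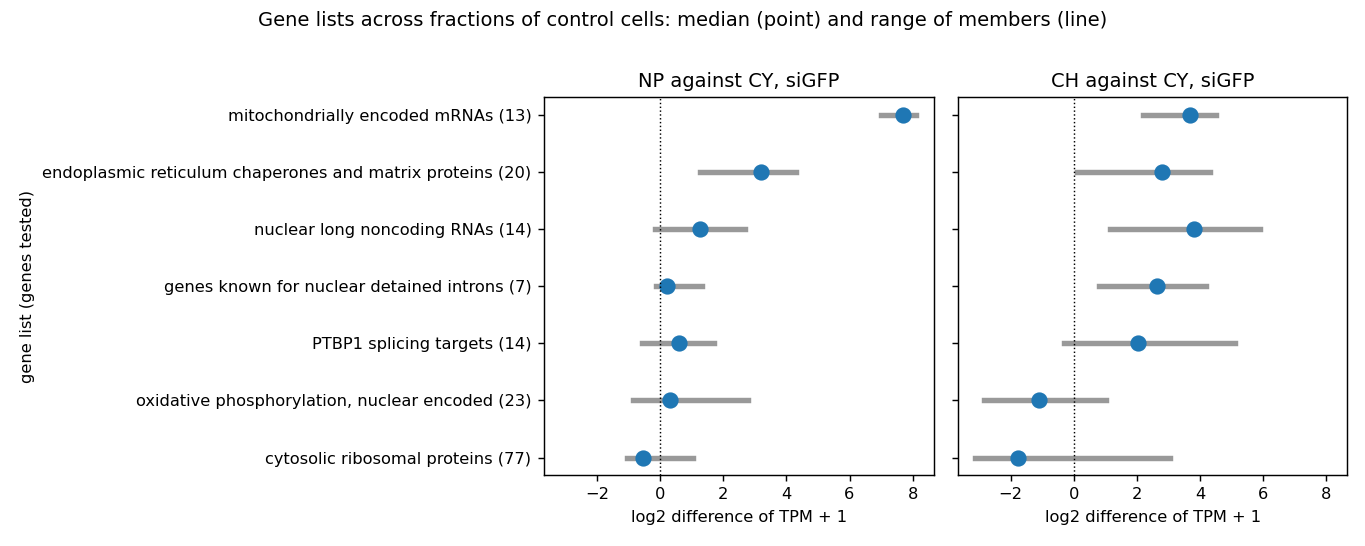
Log2 difference of TPM + 1 (horizontal axis) of NP against CY and of CH against CY in siGFP for 7 gene lists (vertical axis, with the genes tested); points are medians and lines the range of members. Ribosomal proteins have a median of -1.76 in CH against CY, where the median of all genes was 0.95 and moved to -0.12 with quantile normalization.

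The difference of the siPTBP1 effect between CH and CY asked which cytoplasmic changes were not matched on chromatin. Fmnl3, which fell in CY, was not called in CH, where it had 37.7 ± 8.21 against 40.9 ± 6.04 TPM. Its effect was higher in CH by 1.97 on the log2 scale (adjusted p = 0.00881). In the double knockdown its level in CH was 41.2 ± 4.87 TPM and the difference 2.00 (adjusted p = 0.00735). Vamp2 in CH had 80.7 ± 17.9 against 72.8 ± 15.8 TPM, and its difference of -1.47 was called only with the block (adjusted p = 0.234, 0.00868 with the block). So were those of Gabbr1 after siPTBP1 (-1.62, 0.0134 with the block) and of Flna in the double knockdown (1.63, 0.0398 with the block). Of 14 PTBP1 splicing targets 1 was higher and 4 were lower adjusted over the list alone. With 6 genes higher and 3 lower after siPTBP1 and 9 and 3 in the double knockdown, the counts were small; with the block they were 28 and 12, and 70 and 9. With quantile normalization the siPTBP1 calls divided into 3 and 3 and those of the double knockdown into 11 and 2. For Fmnl3 the call was lost with median-ratio scaling (0.0539 and 0.0806) and quantile normalization (0.205 and 0.182), and in the double knockdown without all replicate 1 libraries (0.0531). The scalings left differences of 2.08 and 1.75 after siPTBP1 and 1.96 and 1.70 in the double knockdown, and the calls ended mainly because the standard error rose from 0.307 to 0.404 and 0.393. The siPTBP1 count was 23 without siGFP CH replicate 1, 21 without siGFP CH replicate 2, 17 without siPTBP1 CH replicate 1 and 16 without siPTBP1 CH replicate 2. The double knockdown's was 22 without siGFP CH replicate 2, 31 without double knockdown CH replicate 2, 7 without siGFP CY replicate 2, 5 without siGFP CY replicate 3 and 7 without double knockdown CY replicate 3.

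**Figure D4:**
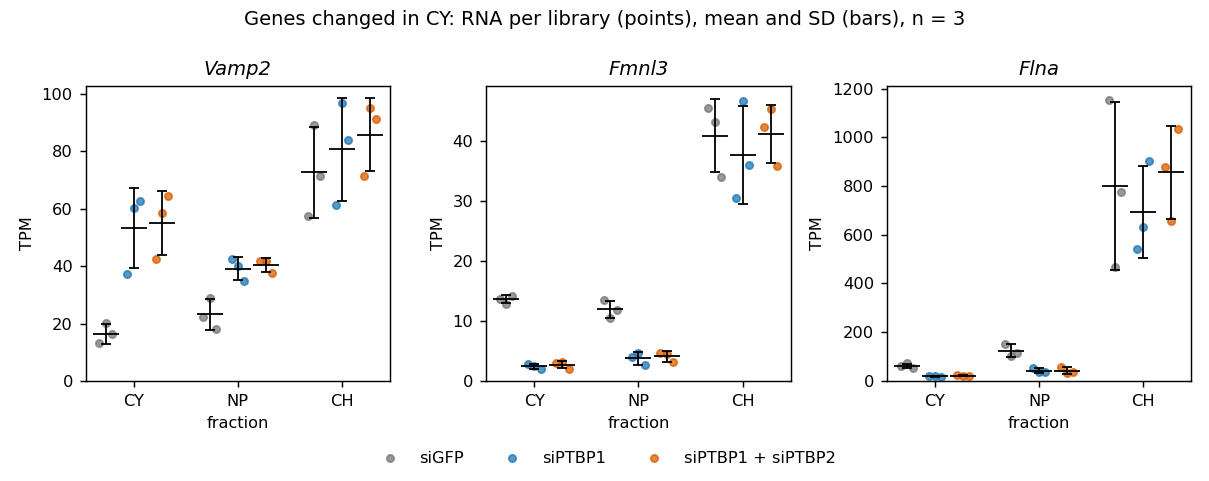
RNA of Vamp2, Fmnl3 and Flna in TPM (vertical axis) by fraction (horizontal axis) and treatment (colours); points are libraries, and bars are means with SD of 3. Fmnl3 fell from 13.6 to 2.44 TPM in CY and stood at 40.9 and 37.7 TPM in CH; the difference for Fmnl3 was called with TPM as deposited and with the block, but not with median-ratio scaling or quantile normalization without it.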

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

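Tests of GC content as part cause, precision in CH, scaling for Vamp2 and Fmnl3 and whole-cell levels were chosen after the result was seen. So were the simulations across fractions and the settings with a replicate block within fraction and without the replicate 1 libraries.

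In each of the 9 groups the replicate 1 library stood apart and had the highest Mir6236 share and fewest genes at 1 TPM. On the component with 39.4% of the variance within groups the gap between scores was 50.3. After each library's trend with GC content was removed, all 9 replicate 1 libraries still lay beyond the other 18, with a gap of 34.3 on a component with 26.7% of the variance. After the trend with transcript length was removed 9 did, with a gap of 38.9 and 35.2%, which argues against either trend as the whole cause. A GC trend may be part of the cause. Each replicate 1 deviation rose with GC content (r of at least 0.277), although centring forces the opposite sign on the others. Differences of culture, day or library batch stay open, since the labels give none. Neither library or RNA quality nor a biological explanation was tested.

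Vamp2 and Fmnl3 changed in CY and were not called in CH. Too little precision in CH is argued against: adjusted over all genes, which allows for the choice of these, the difference had an adjusted p of 0.00868 for Vamp2 and 0.000161 for Fmnl3 with the replicate block (0.234 and 0.00881 without), and the 95% intervals in CH ran from -0.23 to 0.52 and -0.46 to 0.21, against 1.62 and -2.09 in CY. Scaling of the libraries is argued against too, with a largest adjusted p of 0.0230 for the difference over both scalings with the replicate block; without the block both scalings ended the call of Fmnl3, whose difference went from 1.97 (SE 0.307) to 2.08 (0.404) and 1.75 (0.393) after siPTBP1, and over all settings its adjusted p ran from 0.000111 to 0.205 after siPTBP1. RNAs rising in CY after siPTBP1 may be held on chromatin in control cells. This predicted a high CH to NP ratio in siGFP for the 275 genes called higher with the block. Their median of 0.37 lay at percentile 0 of 10000 expression-matched lists, whose median was 0.66. Calls in CY require expression there, which may lower this ratio, so the test cannot decide. A change of export, decay or later splicing may underlie both genes.

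The endoplasmic reticulum list and, in the double knockdown, that of mitochondrially encoded mRNAs were shifted upward in NP after knockdown, with no member called without the block and no list call with an estimated correlation (0.233 for the first after siPTBP1, 0.273 and 0.406 in the double knockdown). More of these organelles carried into the NP fraction may be the cause: across genes the siPTBP1 change in NP ran with the enrichment in NP over CY measured in the double knockdown with r = 0.293, against -0.0120 for the change in CY and 0.115 in CH. The double knockdown libraries share the NP change, which raises that r; against the enrichment in siGFP, where shared controls lower it, r was 0.156 in NP, and it was 0.140 in CY, where they raise it. Higher levels of these RNAs in the whole cell cannot be told apart from carry-over, because the endoplasmic reticulum list had a median of 0.207 in CY and 0.289 in CH against 0.505 in NP, and the interval of its excess over 0.5 of the NP change included 0 in CY (-0.167 to 0.0345) and in CH (-0.0737 to 0.119). A response of the cells to lower Ptbp1 stays open as the biological explanation and was not tested apart from these.

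A test of the difference between the effects in CH and in CY made each of the following results stand out. It called 9 genes for siPTBP1 and 12 for the double knockdown. For siPTBP1, Mir6387 (difference 3.23), Trav12d-3 (2.62) and Fmnl3 (1.97) were among those called. Over the settings their adjusted p ran from 0.000262 to 0.514, 0.000122 to 0.268 and 0.000111 to 0.205. For the double knockdown they included Mir3109 (3.55), Trav12d-3 (2.78), Fmnl3 (2.00), Aldh9a1 (1.92) and Abhd14b (1.85). There the ranges were 0.00438 to 0.45, 4.26e-05 to 0.142, 4.26e-05 to 0.182, 0.000225 to 0.45 and 8.06e-05 to 0.263. Also called were genes outside the rule for named genes, chosen after their values were seen: Gm25016, Gm22051, Gm27688, Gm27365 and Gm44324 for siPTBP1, and Gm24061, Gm25016, Gm22932, Gm27365, 1700015C17Rik and Gm44465 for the double knockdown. Mir6387 and Mir3109 have transcripts under 200 nt. Against siGFP libraries listed at 0 the differences of Mir6387, Trav12d-3 and Mir3109 depend on the pseudocount.

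The same test called 4 lists for each treatment with a preset correlation and none with an estimated one. For siPTBP1 these were PTBP1 splicing targets (3.32e-06, median -0.43, 0.176 with an estimated correlation), synapse (4.91e-05, median -0.19, 0.604), SRF and YAP targets (0.000216, median -0.38, 0.761) and, upward, mitochondrially encoded mRNAs (0.000493, median 0.78, 0.824). Without the replicate 1 libraries the last had a median of 0.07 and an adjusted p of 0.940. For the double knockdown they were PTBP1 splicing targets and synapse (0.000131 each, medians -0.35 and -0.11, 0.517 and 0.668), SRF and YAP targets and oxidative phosphorylation, nuclear encoded (0.0038 each, medians -0.37 and -0.27, 0.829 and 0.872).

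The libraries of each contrast were also divided in all other ways. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. After siPTBP1 the numbers of splits with as many genes as the real one were 1 in CY (47 genes, highest other 0), 1 in NP (33, highest other 6) and 3 in CH (82, highest other 1112). For the double knockdown they were 1 in CY (50, highest other 2), 1 in NP (32, highest other 4) and 2 in CH (88, highest other 262). For the double knockdown against siPTBP1 they were 10 in CY (0 genes in limma, 147 at an unadjusted p under 0.05, a share of all genes below 0.05, highest other 3), 6 in NP (1, highest other 8) and 10 in CH (22, highest other 280). The splits of CH that called several times the real count point to a structure of the samples other than the treatments. Among splits that part every pair of libraries with the same number the highest other was 20 after siPTBP1, 30 in the double knockdown and 46 between the knockdowns. For the fractions each real split stood alone with 1: NP against CY with 2638 genes (highest other 3), CH against CY with 13607 (2) and CH against NP with 10609 (10). For the difference between CH and CY, 30 of 100 splits drawn called at least the 9 genes of siPTBP1 (highest other 89) and 20 of 100 at least the 12 of the double knockdown (highest other 153), so chance cannot be excluded for these counts. Among those that part every pair of libraries with the same number, 14 and 18 of the splits drawn, the highest other was 9 and 116.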

How the results depend on the processing

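Both settings chosen after seeing the data were the replicate block within fraction and the removal of the replicate 1 libraries. Counts are given in the order siPTBP1 in CY, NP and CH, double knockdown in CY, NP and CH, double knockdown against siPTBP1 in CY, NP and CH, NP against CY, and the difference between CH and CY for siPTBP1 and the double knockdown, and any not listed stayed within 1.5 times. The replicate block called 377, 388 and 505, 547, 379 and 436, 1 in CY of the double knockdown against siPTBP1, 5830 and 40 and 79. The replicate block within fraction called 1162, 1447 and 1273, 1550, 1532 and 1365, 2, 2 and 36, 6395 and 160 and 233. Without the replicate 1 libraries there were 95, 111 and 182, 101, 93 and 198, 2, 7 and 38, 4435 and 50 and 42. The culture block gave 35 for siPTBP1 CH, 30 for double knockdown CH, 0 and 10 for double knockdown against siPTBP1 in NP and CH, 4901, and 37 and 56. A fit of the fractions compared only gave 14 and 7 for siPTBP1 NP and CH, 31, 6 and 2 for the double knockdown, 2, 6 and 2 against siPTBP1, and 7 for the difference in the double knockdown. With a TPM of at least 5 in at least 3 libraries siPTBP1 NP and CH gave 19 and 35, double knockdown NP and CH 21 and 20, and double knockdown against siPTBP1 2 in NP and 8 in CH. With no filter siPTBP1 CH gave 391, double knockdown CH 384, double knockdown against siPTBP1 1 in CY and 135 in CH, and the differences 50 and 63. With a pseudocount of 0.1 siPTBP1 CH gave 32, double knockdown CH 28, double knockdown against siPTBP1 2 in CY and 3 in NP, and the difference in the double knockdown 7, and the correlation of both effects in NP was 0.634. Median-ratio scaling gave 63 and 48 for siPTBP1 NP and CH, 55 and 41 for double knockdown NP and CH, 2 against siPTBP1 in NP, and 19 for the difference in the double knockdown. Quantile normalization gave 54 for siPTBP1 NP, 52 and 53 for double knockdown NP and CH, and 0 and 14 against siPTBP1 in NP and CH. Without mitochondrially encoded genes 2 genes were called in NP of the double knockdown against siPTBP1, and 7 for the difference in the double knockdown. Leaving out each library in turn gave 22 to 39, 17 to 35 and 62 to 184 genes for siPTBP1, 21 to 51, 19 to 29 and 50 to 181 for the double knockdown, 0 to 3, 0 to 6 and 31 to 65 between the knockdowns, 1803 to 2456 for NP against CY, 12179 to 13513 for CH against CY, 8874 to 10839 for CH against NP, and 8 to 23 and 5 to 31 for the differences. Of the gene list tests 108 passed, 13 with an estimated correlation and 87 to 135 with the other settings. Directions turned for ribosomal proteins after siPTBP1 in CH (6.86e-07), mitochondrially encoded mRNAs there (0.747) and ribosomal proteins between the knockdowns in CY (0.268) without the replicate 1 libraries, and for hnRNP proteins in NP against CY (0.338) with the replicate block within fraction. With quantile normalization they turned for glycolysis (0.732) and hnRNP proteins (0.859) in CH against CY, glycolysis in CH against NP (0.487), Pkm (0.97) in CH against CY and Sv2a (-0.64) in CH against NP. Of 584 named gene results, the replicate block called 77 more and ended 3, a fit of the fractions compared only called 5 more and ended 70, median-ratio scaling 9 and 32, quantile normalization 7 and 43, and the removal of the replicate 1 libraries 33 and 33. Beyond the calls given with their blocked values, the replicate block changed no other call of a gene or list whose test is printed in the report. The gene list tests were not run with the culture block, which that test does not take. The counts of CH against CY and CH against NP stayed within 1.5 times under every setting run. The depth of the libraries is unknown, so what it limits was not measured. The cause of these dependences was not tested.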

Other observations

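On chromatin of siGFP cells Meg3 and Mirg, of an imprinted locus on chromosome 12, were above CY. Meg3 (ENSMUSG00000021268, 109541001 to 109571726, plus strand), a maternally expressed long noncoding RNA, had 1371 ± 369 TPM in CH against 37.4 ± 7.84 in CY (5.14, adjusted p = 2.13e-11), and Mirg (ENSMUSG00000097391, 109729764 to 109749460, plus strand), a microRNA host transcript on the same strand, had 229 ± 77.4 against 6.20 ± 1.65 (4.96, adjusted p = 1.1e-10). Both passed under all settings run, with adjusted p up to 4.54e-08 and 3.66e-08. Between them lie precursors of the same strand that went opposite ways after siPTBP1 in CH: Mir654 (109723218 to 109723301) rose from 7.31 ± 6.98 to 43.9 ± 9.83 TPM (3.11, adjusted p = 0.0136) and Mir666 (109717085 to 109717183) fell from 30.8 ± 14.2 to 5.07 ± 4.4 (-2.79, adjusted p = 0.0222). Both are shorter than 200 nt. Over the settings their adjusted p reached 1 with a fit of the fractions compared only, and Mir666 was not called without siGFP CH replicate 2 (0.0682) or siGFP CH replicate 3 (0.0965).

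Neuronal and mesenchymal RNAs of low abundance in the cytoplasm of these stem cells were also found on chromatin. Stx1a, a syntaxin of neurons, had 35.3 ± 4.55 TPM in CH against 3.87 ± 0.801 in CY (2.90, adjusted p = 2e-10), Elavl3, a neuronal RNA binding protein, 23.5 ± 6.39 against 3.55 ± 0.813 (2.41, adjusted p = 4.42e-08) and Celf4, a neuronal splicing regulator, 13.6 ± 2.33 against 1.71 ± 0.467 (2.42, adjusted p = 4.22e-09). Col1a1, a fibrillar collagen, had 63.9 ± 35.3 against 1.03 ± 0.104 TPM (4.87, adjusted p = 3.51e-09) and Col1a2 21.4 ± 7.57 against 0.32 ± 0.226 (4.05, adjusted p = 9.47e-10). These 5 genes were called under all settings run, with adjusted p up to 2.06e-05, 0.000564, 0.000552, 3.35e-06 and 3.41e-06. Of 23 synapse genes 17 were higher in CH and 1 lower, and of 13 fibroblast genes 9 were higher and none lower. Neither list lay apart from the other genes by the camera test (adjusted p = 0.166 and 0.149), against a median of all genes of 0.95. Gene TPM does not separate nascent from retained RNA, so the form of these transcripts is open.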
